A study of Mus musculus with 20 samples.

How the data were processed

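RNA was sequenced from bilateral amygdala punches of 20 male mice, 5 in each of 4 groups made of F1 or F2 generation and stress or no-stress lineage. Libraries were made with a stranded poly-A protocol (TruSeq Stranded mRNA). Per the submitters' processing notes, reads were aligned with STAR 2.5.3a to GRCm38. The counting tool, the annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited values are counts, whole numbers per Ensembl gene and mouse, for 29671 genes with at least 1 count in some library. The column totals ran from 13654890 to 13714805, so the libraries had been brought to a common total by a step that the labels do not describe. The depth before that step is not known and may have differed between groups. Each mouse had its own replicate number from 1 to 20, so no mice were paired. The labels name no batch, date, litter or sire. Littermates within a group, if any, would be less independent than the tests with n = 5 assume.

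The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersion, TMM factors (0.956 to 1.042), genes kept by filterByExpr (16727 genes), 1 mean per group and all 20 libraries in 1 fit. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The 5 comparisons were stress against no-stress lineage in F1 and in F2, the difference between these effects, their mean, and F2 against F1 within the no-stress lineage. CPM are given as means ± SD of 5 mice, and log2 fold changes with the SE of the fit. F1 and F2 fold changes were correlated across genes and set against 100 relabellings within each generation.

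In all, 36 gene lists of functions, cell types, regions and quality were tested with camera of limma 3.58.1, with a preset inter-gene correlation of 0.01 and with an estimated one, and with fry, adjusted over the lists. Members were also adjusted over the list alone. A list score was the mean log2 CPM of its members (prior count 2), compared by an exact two-sided permutation test of 5 against 5 libraries (252 arrangements, smallest p 0.00794). The lists, the comparisons and tests, the other settings and the rule for named genes were fixed before the data were examined. The rule takes the 12 higher and 12 lower called genes with the smallest p and a mean CPM of at least 1 in F1 and F2 (5 and 5 elsewhere, and 5 as values where fewer pass), up to 4 members per list, and always Crh, Crhr1, Nr3c1, Fkbp5, Bdnf and Oxtr. Genes without a name were counted and passed over.

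The other settings fixed then were DESeq2 1.42.0, limma-voom without and with library weights, relative log expression and upper-quartile factors, library totals, no low-count filter, a filter of CPM of at least 1 in at least 5 libraries, 1 surrogate variable (sva 3.50.0), a component of the region and cell type scores centred within groups, only the groups compared in the fit, an adjusted p of 0.1, a 1.2-fold minimum, and each library left out in turn. A planned variant for normalized values was not run, because the values are counts. Settings added after the data were seen were an offset of each library's trend with GC content and transcript length (splines with 5 degrees of freedom; GC content known for 16692 genes), the first 2 composition components without centring, the removal of mitochondrial genes and their nuclear copies, and the removal of F2 stress replicate 14 and F2 no-stress replicate 20, the libraries lowest in striatal and in basolateral amygdala scores. Figures were drawn with Python 3.11.15.

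The fits were tested on simulated data. Of 100 genes changed 1.5-fold in F2, 36 were called, and of 100 changed 2-fold, 80 were called, with 7 calls among unchanged genes; with no change in F1, 0 were called. The fitted trends of the real libraries with GC content and length were also added to the simulated counts. Then 124 unchanged genes were called without the offset and 4 with it, and 80 and 78 of the 2-fold genes were called. The list test called the shifted list and 0 of 35 others. Simulated genes varied independently, so this does not test the preset correlation for lists whose genes vary together. All 20 libraries had Y-linked expression and at most 4 Xist counts, and no pair of libraries was a duplicate (chi-square per gene of at least 5.64 in any pair and at least 6.52 in the 40 pairs within groups). On chromosome 1, 5 nuclear copies of mitochondrial genes took 2.12 to 2.77% of counts. Their counts were nearly equal to those of the mitochondrial genes, as counting shared reads for both would give. A copy was taken as such at a ratio between 0.9 and 1.1 in every library and a mean count of at least 1000. Of the gene symbols, 46 stood in more than 1 row, and each row was tested by its identifier.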

Results

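Messenger RNA was measured in the amygdala, a forebrain structure central to fear and stress responses, of 20 male C57B6 mice at postnatal day 84. The mice belonged to the F1 or the F2 generation descended from animals that had gone through chronic unpredictable stress in adolescence, or from animals that had not. Each of the 4 groups (F1 stress, F1 no-stress, F2 stress and F2 no-stress lineage) held 5 mice, and the labels call them biological replicates. The sampled mice had no behavioural testing. The question named by the series title is whether the stress of an ancestor is seen in the amygdala transcriptome of later generations. The count table held 29671 genes and between 13654890 and 13714805 counts per library, a spread of 0.44%, so the totals as given hardly differed between groups. After removal of genes with low counts, 16727 genes were tested, and the biological coefficient of variation between mice of a group was 18.1%.

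In the F2 generation, mice of the stress lineage differed from mice of the no-stress lineage in 1324 genes, or 7.92% of those tested (edgeR quasi-likelihood test, adjusted p below 0.05). Of these, 441 were higher and 883 were lower in the stress lineage, and their median absolute log2 fold change was 0.443, with 69 genes changing at least 2-fold. Nxph2, which encodes a neurexophilin, a secreted ligand of neurexins, showed the largest rise among the 12 higher genes with the smallest p, from 1.86 ± 0.526 to 4.83 ± 1.27 CPM (mean ± SD, n = 5 in each group; log2 fold change 1.37 ± 0.26 SE, adjusted p = 0.00755). Inha, the inhibin alpha subunit, fell from 18.2 ± 3.76 to 9.13 ± 1.28 CPM (n = 5 each; log2 fold change −0.99 ± 0.15 SE, adjusted p = 0.0056). Acaa1a, a peroxisomal thiolase of fatty acid oxidation, fell from 54.3 ± 6.30 to 33.3 ± 2.97 CPM (log2 fold change −0.71 ± 0.10 SE, adjusted p = 0.0056). For these 3 genes all 5 libraries of a group lay beyond all libraries of the other group. They were picked by p in the same libraries, which favours such a separation, so it adds no support.

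The other higher genes were the Wnt receptor gene Fzd4 (log2 fold change 0.54), Nkain2 (0.43), Ndfip1, an adaptor of ubiquitin ligases (0.43), the nucleotide synthesis gene Prps1 (0.41), Lrrc40 (0.38), Pdcd10 (0.37), Tmed7 (0.37), Itfg1 (0.35), the transcription elongation factor gene Tcea1 (0.34), Naa50 (0.34) and the sphingosine phosphate phosphatase gene Sgpp1 (0.31). The other lower genes were Wdr90 (−0.92), Rabep2 (−0.91), the axonal spectrin gene Sptbn4 (−0.89), Dus3l (−0.81), Zfp653 (−0.75), Ighmbp2 (−0.61), Gtpbp2 (−0.61), the zinc transporter gene Slc39a13 (−0.59), the fringe glycosyltransferase gene Rfng (−0.41) and Trim41 (−0.38). Adjusted p for these 24 genes ran from 0.0056 to 0.0114. A further 59 called genes carried no gene name. Nxph2 (ENSMUSG00000069132) lies on chromosome 2 (23321246 to 23401973), Inha (ENSMUSG00000032968) on chromosome 1 (75507077 to 75510366) and Acaa1a (ENSMUSG00000036138) on chromosome 9 (119339676 to 119350299) of GRCm38, and all are protein-coding. Of the 52 named genes called in F2, 29 kept their call whichever library was left out and 23 lost it at least once.

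**Figure D1:**
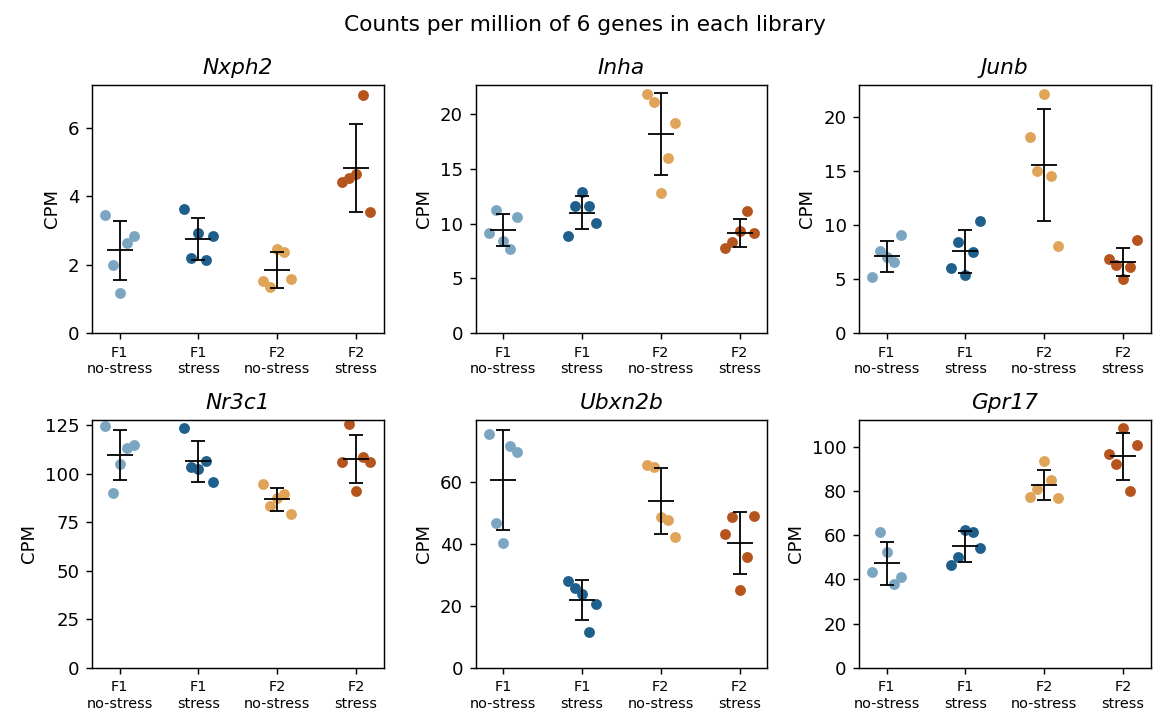
Expression of 6 genes as counts scaled to library size (CPM, y axis from 0) in each of the 20 libraries (points) by generation and lineage, with the group mean and SD as bars (n = 5). Inha and Junb are highest in the F2 no-stress group, at means of 18.2 and 15.6 CPM, Ubxn2b is lowest in the F1 stress group, at 21.9 CPM, and Gpr17 is higher in both F2 groups than in both F1 groups.

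Of 22 immediate early genes, which are induced within minutes of neuronal firing, 3 fell and 19 did not pass the test. Junb fell from 15.6 ± 5.17 to 6.57 ± 1.32 CPM (n = 5 each; log2 fold change −1.24 ± 0.23 SE, adjusted p = 0.00739), Npas4 had a log2 fold change of −1.003 ± 0.255 (adjusted p = 0.023) and Ier2 one of −0.996 ± 0.248 (adjusted p = 0.0207). Of 33 genes of glutamate receptors and transporters, 5 fell and 0 rose. They included the postsynaptic scaffold gene Shank1 (−0.76), the NMDA receptor subunit genes Grin2c (−0.66) and Grin1 (−0.42), and the kainate receptor subunit gene Grik5 (−0.62). Vgf, a neuropeptide precursor induced by neurotrophins, fell by 0.72 on the log2 scale. With the trends with GC content and transcript length entered, none of these 8 genes kept its call. The values were −0.77 for Junb (adjusted p = 0.0578), −0.76 for Npas4 (0.197) and −0.57 for Ier2 (0.261). They were −0.26 for Shank1, −0.18 for Grin2c, −0.01 for Grin1, −0.15 for Grik5 and −0.18 for Vgf (adjusted p from 0.434 to 0.961). Adjusted over the list alone, 4 immediate early genes and 6 glutamate genes were lower, and 0 and 1 were higher.

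Of 44 enzymes of DNA methylation and histone modification, 5 fell and 1 rose in F2. The histone deacetylase gene Hdac5 fell from 112.8 ± 9.64 to 70.4 ± 14.5 CPM (n = 5 each; log2 fold change −0.68 ± 0.12 SE, adjusted p = 0.00662), and Kdm6b (−0.59), Ehmt2 (−0.52) and Kmt2b (−0.47) were also lower. With the same trends entered, the values were −0.16 for Kdm6b, −0.09 for Ehmt2 and −0.05 for Kmt2b (adjusted p from 0.558 to 0.819). Adjusted over the list alone, 8 of these enzymes were lower and 1 was higher. Of 16 genes of the hypothalamic-pituitary-adrenal axis, only the glucocorticoid receptor gene Nr3c1 passed, rising from 86.7 ± 5.85 to 107.4 ± 12.3 CPM (n = 5 each; log2 fold change 0.31 ± 0.09 SE, adjusted p = 0.0478), and 0 passed when adjusted over the list alone. Given as values without a call, the F2 log2 fold changes of Crh (0.11 ± 0.27 SE), Crhr1 (−0.19 ± 0.18), Fkbp5 (−0.12 ± 0.12), Bdnf (0.39 ± 0.52) and Oxtr (0.48 ± 0.25) had adjusted p from 0.23 to 0.83, and that of Crhr1 was 0.14 with the correction for GC content.

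Single members of other lists passed in F2 in both directions. Higher genes were the glucocorticoid-responsive Errfi1 (0.38), the imprinted ubiquitin ligase gene Ube3a (0.32), Uqcrc2 (0.28) and Cycs (0.25) of the respiratory chain, the interferon-induced Ifit2 (0.49), the chaperone genes Hspd1 (0.26) and Dnaja1 (0.33), and the Y-linked Ddx3y (0.38). Lower genes were Ndufb7 (−0.54) of the respiratory chain, the brain matrix gene Bcan (−0.52), Egfl7 (−0.57), Tie1 (−0.58) and Cldn5 (−0.49) of endothelial cells, Wfs1 (−0.50) and the ribosomal protein gene Rpl36 (−0.93). With the trends with GC content and length entered, all 15 lost their call (adjusted p from 0.0918 to 0.748), with values such as −0.11 for Bcan, −0.11 for Cldn5, −0.16 for Wfs1, 0.09 for Cycs and 0.12 for Uqcrc2. Others changed less, such as 0.33 for Errfi1, 0.26 for Ube3a, 0.31 for Ddx3y, 0.36 for Ifit2 and −0.39 for Ndufb7. No list as a whole passed in F2 (camera with a preset correlation of 0.01, 36 lists, adjusted p from 0.209 to 0.972), and none did with an estimated correlation (smallest adjusted p = 0.985). No list score per library had an exact p below 0.05 in F2 (permutation test, two-sided, smallest adjusted p 0.816), in a design whose smallest p of 0.00794 lets no single list pass after adjustment over 36. Without F2 stress replicates 12, 14 and 15 and F2 no-stress replicate 18, in turn, 1, 2, 1 and 2 lists passed with the preset correlation.

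The direction of the F2 changes went with the base composition of the transcripts. The genes lower in the stress lineage had a median GC content of 57.8%, the higher genes 43.0% and the genes not called 49.2%. Across genes, which are not independent replicates, log2 fold change and GC content had a Spearman rho of −0.539. The libraries themselves differed in this respect. With genes in 10 bins of GC content, the median log2 deviation in the highest minus that in the lowest bin averaged −0.19 ± 0.26 in the F2 stress and 0.34 ± 0.27 in the F2 no-stress libraries (SD, n = 5 each; exact permutation test, two-sided, p = 0.0159). Stress replicate 15, at 0.21, and no-stress replicate 20, at −0.10, went against their groups. With each library's trend with GC content and transcript length entered as an offset, 13 genes passed and 9 of the 1324 kept their call. The median absolute log2 fold change of the 1324 went from 0.443 to 0.215. Of the 24 genes with the smallest p only Acaa1a kept its call (log2 fold change −0.48, adjusted p = 0.0419). Nxph2 (1.24, adjusted p = 0.0578) and Fzd4 (0.50, adjusted p = 0.0546) lost theirs with values close to the uncorrected ones. The values were −0.65 for Inha, −0.77 for Junb, −0.27 for Hdac5 and 0.18 for Nr3c1, with adjusted p of 0.0791, 0.0578, 0.0924 and 0.395.

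**Figure D2:**
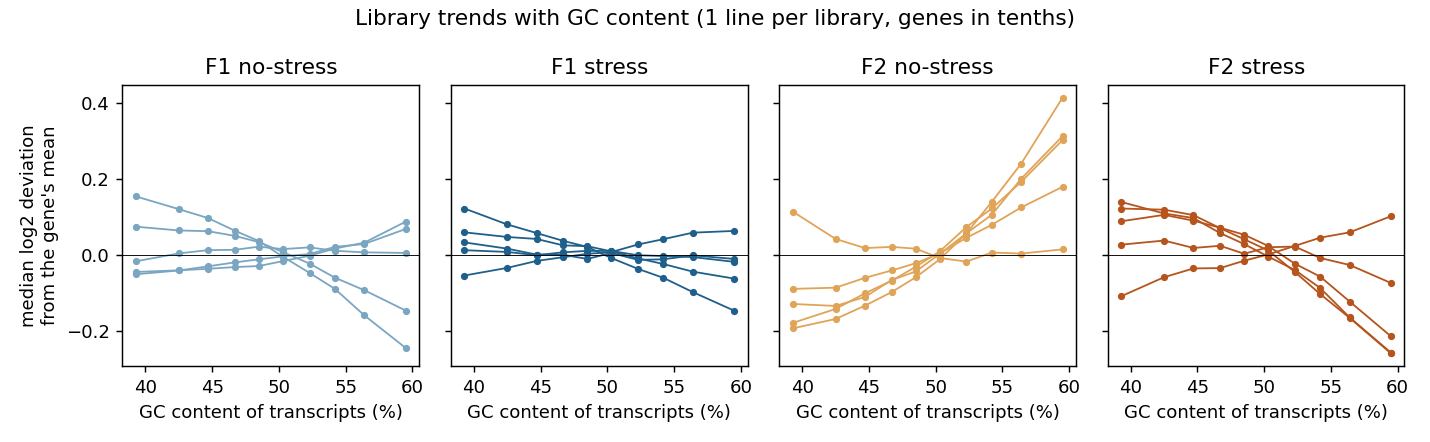
Median log2 deviation of genes from their mean over all libraries (y axis) in 10 bins of genes by GC content of the longest transcript (x axis, %), with 1 line per library and 1 panel per group. In 4 of 5 F2 no-stress libraries the line rises with GC content, and in 4 of 5 F2 stress libraries it falls.

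**Figure D3:**
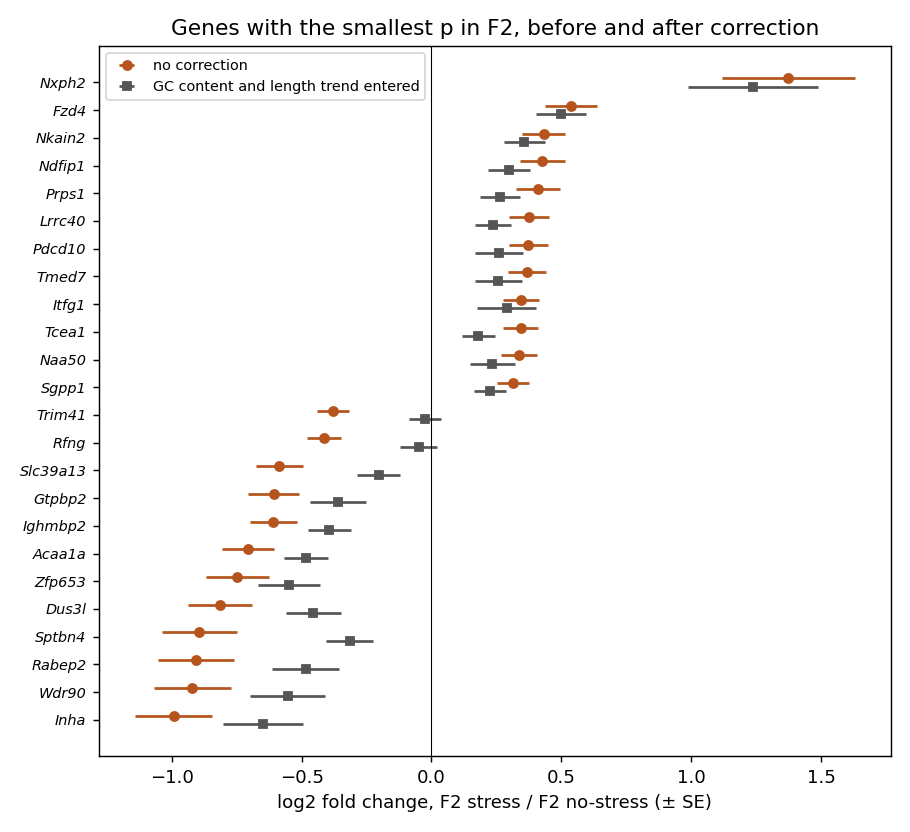
Log2 fold change between F2 stress and F2 no-stress lineage (x axis, bars are SE) of the 12 higher and 12 lower genes with the smallest p, without correction (circles) and with each library's trend with GC content and length entered (squares). All 24 values lie nearer to 0 after correction.

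The F2 count also depended on the libraries in the fit. With only the 10 F2 libraries in the fit 0 genes passed, with 3216 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0765, against 2054 genes in DESeq2 and 1285 in limma-voom with all 20. It was 241, 511, 556 and 2431 without F2 stress replicates 11, 12, 13 and 15, and 421 and 358 without F2 no-stress replicates 16 and 17.

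In the F1 generation, no gene passed the test between the stress and the no-stress lineage, with 1030 genes at an unadjusted p below 0.05 (edgeR). DESeq2 called 2 genes, limma-voom 0 and limma-voom with library weights 3. The gene with the smallest p was Ubxn2b (ENSMUSG00000028243; GRCm38 chromosome 4, 6191098 to 6221688), which encodes a cofactor of the ATPase Vcp. Its level was 60.6 ± 16.1 CPM in the no-stress and 21.9 ± 6.41 CPM in the stress lineage (n = 5 each; log2 fold change −1.47 ± 0.23 SE, adjusted p = 0.0726), and it was lower in 5 of 5 stress libraries than in any no-stress library. The choice by p in the same libraries favours such a separation, which therefore adds no support. Ubxn2b passed in DESeq2 (adjusted p = 3.72e-06), in limma-voom with library weights, with library totals as scaling (adjusted p = 0.039), with a component of regional composition in the model (0.0186) and without F1 no-stress replicate 7 (0.0284). Neither it nor any gene passed with the GC and length offset, 1 surrogate variable, only the F1 groups in the fit or no low-count filter. The smallest adjusted p in these edgeR fits were 0.128, 0.337, 0.412 and 0.22, and in limma-voom without weights 0.104. Without any other single F1 library no gene passed either. The F2 levels of Ubxn2b were 53.7 ± 10.6 and 40.3 ± 10 CPM. The next lower genes were Tmem267 (log2 fold change −0.81 ± 0.16 SE), Ccdc122 (−1.12 ± 0.29), Oard1 (−0.46 ± 0.11) and Zfp931 (−0.45 ± 0.12). The 5 with the smallest p on the other side were Ankrd23 (1.04 ± 0.30), Pmf1 (0.67 ± 0.20), Nat8f7 (0.59 ± 0.18), Zc3h3 (0.52 ± 0.15) and the teneurin gene Tenm3 (0.34 ± 0.096). None of these passed in edgeR (adjusted p = 0.542 for Tmem267 and 0.739 for the others). Tmem267 passed in DESeq2 (0.0163) and, like Ccdc122, in limma-voom with library weights (0.0417 for both).

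Stress-axis genes had no call in F1. The log2 fold changes were 0.28 ± 0.27 (SE) for Crh, 0.22 ± 0.18 for Crhr1, −0.04 ± 0.09 for Nr3c1, −0.02 ± 0.12 for Fkbp5, 0.33 ± 0.52 for Bdnf and 0.19 ± 0.25 for Oxtr, with adjusted p from 0.757 to 0.976. The Fkbp5 value was 0.02 with library totals as scaling.

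Lists of oxidative phosphorylation, ribosomal protein and mitochondrially encoded genes passed as lower in the F1 stress lineage with the preset correlation, and none did with an estimated correlation (adjusted p = 0.776 for each). Of 75 nuclear-encoded genes of oxidative phosphorylation, 72 had a negative log2 fold change, with a median of −0.22, for example Cox7b (−0.33 ± 0.09 SE) and Uqcrh (−0.36 ± 0.10), subunits of complexes of the respiratory chain. None of the 75 passed over all genes tested, and 16 were lower when adjusted over the list alone. Of 80 ribosomal protein genes, 78 were negative (median −0.21), for example Rps24 (−0.36 ± 0.10) and Rpl31 (−0.39 ± 0.12). Reads of such genes can be shared with processed pseudogenes. All 15 mitochondrially encoded genes were negative (median −0.28), with mt-Nd1 at −0.45 ± 0.15 and mt-Nd2 at −0.41 ± 0.15, and 5 of them had nearly the same counts as their nuclear copies. Mitochondrial genes took 7.16 ± 0.735% of counts in the stress and 8.49 ± 0.789% in the no-stress libraries (SD, n = 5 each; exact permutation test, two-sided, p = 0.0317).

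Of 10 lists of cell types and 7 of regions, 1 each passed in F1 with the preset correlation, microglia and striatal neurons, and none with an estimated correlation (adjusted p = 0.776 for both). All 18 markers of striatal medium spiny neurons, the main cells of the neighbouring striatum, were negative in F1 (median −0.85), for example Gng7 (−0.83 ± 0.43 SE) and Ido1 (−1.21 ± 0.64). All 18 tested rows of the microglial list, which holds 17 symbols, were negative (median −0.19), for example Siglech (−0.26 ± 0.12) and Trem2 (−0.37 ± 0.19). Of 37 imprinted genes 30 were positive (median 0.18), with Mirg at 0.66 ± 0.32 and Rasgrf1 at 0.21 ± 0.10. Of 44 enzymes of DNA methylation and histone modification 30 were positive (median 0.06), with Dnmt1 at 0.26 and Hdac7 at 0.47. In all, 7 lists passed in F1 with the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.776). With the preset correlation the adjusted p was 1.15e-25 for oxidative phosphorylation, 2.72e-22 for ribosomal proteins, 5.91e-09 for mitochondrial genes, 5.59e-06 for striatal neurons, 7.57e-05 for microglia, 8.45e-04 for imprinted genes and 0.0332 for the modifying enzymes (0.654 with the trends with GC content and length subtracted). With 1 surrogate variable in the model, the mean log2 difference of the striatal list turned from −0.81 to 0.14 (camera, adjusted p = 0.026). That of the imprinted list went from 0.26 to 0.004 (camera, adjusted p = 0.642). Of 36 list scores, 3 had an unadjusted p below 0.05 (exact permutation tests, two-sided, smallest adjusted p 0.393), and no single list could pass after adjustment at the smallest p of 0.00794. The striatal score, a mean log2 CPM, was 6.28 ± 0.603 in the stress and 7.10 ± 0.803 in the no-stress libraries (SD, n = 5 each; exact permutation test p = 0.111).

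**Figure D4:**
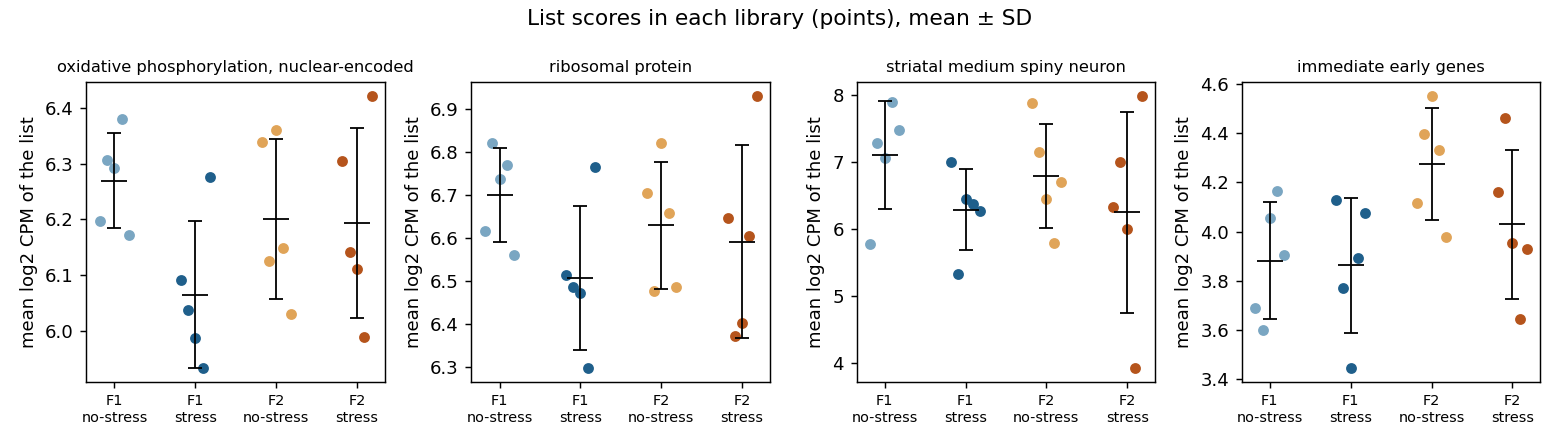
Mean log2 CPM of 4 gene lists (y axis, which does not start at 0) in each library (points) by group, with mean and SD as bars (n = 5). The oxidative phosphorylation score averages 6.07 in F1 stress and 6.27 in F1 no-stress libraries, and the striatal score spans 3.92 to 7.98 over the F2 stress libraries.

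Whether the lineage effect differed between generations was tested as an interaction. It passed in 421 genes, 140 with a higher and 281 with a lower log2 fold change in F2 than in F1. The 5 lower genes with the smallest p were the DNA helicase gene Recql4 (−1.95 ± 0.31 SE), a gene of only 0.714 to 1.84 mean CPM per group, Wdr90 (−1.23 ± 0.21), Inha (−1.22 ± 0.21), the cytoskeletal linker gene Plec (−1.17 ± 0.20) and Gtpbp2 (−0.80 ± 0.14). Positive differences were found in Tmem267 (1.18 ± 0.23), Nkain2 (0.65 ± 0.12), Gtf3c6 (0.65 ± 0.12), the splicing gene Snrpd3 (0.53 ± 0.11) and Timm29 (0.45 ± 0.09), all with adjusted p = 0.0309. From the lists, Junb (−1.34), Shank1 (−1.03), Kmt2d (−0.98), Vgf (−0.85), Kdm6b (−0.74) and Hdac5 (−0.71) were lower. In the other direction, Uqcrb (0.65), Uqcrh (0.57), Cox5a (0.51) and Atp5c1 (0.48) of the respiratory chain and Rpl39 (0.62), Rps24 (0.53), Rpl7 (0.50) and Rpl5 (0.40) of the ribosome were higher.

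At the level of lists, oxidative phosphorylation (58 of 75 genes positive, adjusted p = 2.21e-09), ribosomal proteins (62 of 80, adjusted p = 2.43e-06) and mitochondrially encoded genes (14 of 15, adjusted p = 0.021) were higher in the interaction with the preset correlation. The modifying enzymes were lower (31 of 44 negative, adjusted p = 0.00812), and none of the 4 lists passed with an estimated correlation (smallest adjusted p = 0.966). With the trends with GC content and length subtracted, the modifying enzymes (adjusted p = 0.714) and the mitochondrially encoded genes (0.76) did not pass with the preset correlation. With the GC and length offset 0 genes passed the interaction test (edgeR, smallest adjusted p = 0.0742, 2417 at an unadjusted p below 0.05), against 1240 in DESeq2 and 362 in limma-voom without it. The values were then 0.57 for Nkain2, 1.06 for Tmem267, 0.47 for Timm29 and 0.46 for Snrpd3, close to the uncorrected ones, and −0.42 for Plec and −0.77 for Wdr90. In all, 3551 had an unadjusted p below 0.05 in the uncorrected fit. The count fell to 0 without any 1 of F1 stress replicates 2, 3 and 4, F1 no-stress replicates 7, 8 and 10, F2 stress replicates 11, 12 and 13, and F2 no-stress replicates 16 and 17. It was 855, 1501, 635 and 775 without F1 no-stress replicate 6, F2 stress replicates 14 and 15, and F2 no-stress replicate 18.

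A lineage effect shared by both generations was tested as the mean of the F1 and F2 log2 fold changes, and no gene passed (2361 genes at an unadjusted p below 0.05; edgeR, smallest adjusted p = 0.212 for Ubxn2b). DESeq2 called 36 genes, limma-voom 0 and limma-voom with library weights 532. The averaged log2 fold change of Ubxn2b was −0.94 ± 0.16 (SE), and the next lower genes were the transcription factor gene Etv4 (−0.51 ± 0.11), Zfp653 (−0.44 ± 0.09), Fastk (−0.42 ± 0.09) and Ighmbp2 (−0.30 ± 0.06). On the other side stood Nxph2 (0.78 ± 0.18), the aminopeptidase gene Lnpep (0.29 ± 0.06), Plxdc2 (0.27 ± 0.07), Tmem41b (0.22 ± 0.05) and Pds5b (0.20 ± 0.05). Without F2 stress replicate 15 the count was 490, and without F1 no-stress replicate 7 it was 2, Ubxn2b and Etv4.

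For the averaged effect, 10 lists passed with the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.837). Lower were striatal neuron markers (18 of 18 negative, median −0.52), mitochondrially encoded genes (15 of 15, median −0.13), ribosomal proteins (68 of 80), oxidative phosphorylation (61 of 75), microglia (16 of 18) and immediate early genes (16 of 22). Higher were imprinted genes (29 of 37), genes of GABA signalling (20 of 25), cholesterol synthesis (17 of 21) and the hypothalamic-pituitary-adrenal axis (12 of 16). The immediate early genes did not pass with the GC and length trends subtracted (adjusted p = 0.261). Across genes, which are not independent replicates, the F1 and F2 log2 fold changes had a Pearson r of −0.056 and a Spearman rho of −0.084, and 84 and 79 in 100 relabellings of the libraries within each generation gave values as far from 0. The r was 0.004, 0.097, 0.011 and 0.017 without F2 stress replicates 12 and 15 and F2 no-stress replicates 19 and 20. Of the 1324 genes called in F2, 374 (28.2%) had the same sign in F1.

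Between the generations of the no-stress lineage, 335 genes differed, 246 higher and 89 lower in F2. The largest rise among the named genes was in immediate early genes. Npas4 rose from 7.07 ± 2.94 CPM in F1 to 21.3 ± 4.97 CPM in F2 (SD, n = 5 each; log2 fold change 1.59 ± 0.26 SE, adjusted p = 0.0212), Ier2 by 1.42 ± 0.26 and Junb by 1.13 ± 0.22 on the log2 scale, while 19 of the 22 listed genes did not pass. Gpr17 (ENSMUSG00000052229), a receptor of committed oligodendrocyte precursors, rose from 47.1 ± 9.54 to 82.6 ± 6.86 CPM (n = 5 each; 0.81 ± 0.12 SE, adjusted p = 0.0101), and Neu4, also on the precursor list, rose by 0.58 ± 0.11. Inha (0.95), Zfr2 (0.77) and Rfng (0.44) were higher, as were Hdac5 (0.48), Kdm6b (0.51) and Cldn5 (0.60). Lower genes were Lmbrd2 (−0.45), Pdcd10 (−0.43), Itfg1 (−0.38), the nuclear receptor gene Nr2c2 (−0.36), Emc7 (−0.33), the clock repressor gene Bhlhe41 (−0.51), Uqcrc2 (−0.29) and Ndufs1 (−0.26).

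Immediate early genes (19 of 22 positive), oligodendrocyte precursor markers (10 of 12), markers of mural, fibroblast and meningeal cells (16 of 18) and modifying enzymes (32 of 44) were higher in F2 with the preset correlation. Oxidative phosphorylation (52 of 75 negative) and ribosomal proteins (59 of 80) were lower. Adjusted p ran from 2.95e-04 to 0.0246, and none passed with an estimated correlation (smallest adjusted p = 0.953). By fry for a shift in 1 direction, which does not compare a list with other genes, the precursor list passed (adjusted p = 0.0417). It was the only list to do so in any of the 5 comparisons. For changes in either direction, the fry p, not adjusted over the lists, was 1.65e-05 for immediate early genes here. In F2 it was 1.18e-05 for heat shock genes and 1.33e-05 for the modifying enzymes. The modifying enzymes did not pass with the GC and length trends subtracted (adjusted p = 0.35). Fold changes again followed GC content (Spearman rho 0.477 across genes). With the GC and length offset 9 genes passed and 6 of the 335 kept their call, among them Gpr17 (0.69, adjusted p = 0.0403), while 2 of the 6, Gm28285 and Gm15440, have no known GC content and were not corrected. Npas4 had a value of 1.39 (adjusted p = 0.0716). With only the 10 no-stress libraries in the fit 0 genes passed (3105 at an unadjusted p below 0.05; DESeq2 1028 and limma-voom 294 in all 20 libraries). The count was 725, 4, 0, 209 and 0 without F1 replicates 6, 7, 8, 9 and 10 and 6, 0, 573 and 195 without F2 replicates 16, 17, 18 and 19.

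The F2 no-stress libraries entered both this comparison and the one between F2 lineages. The same 279 genes were called in both, all in opposite directions, where 26.5 would be shared by independent lists. Unchanged groups simulated against shared libraries gave 0 shared calls on average, but their fold changes had a mean r of −0.501 against −0.718 observed, and a covariance of −0.0275 against −0.0702. With the no-stress libraries split 3 and 2 between the comparisons, a mean of 5.8 genes were called in both, all in opposite directions. The mean r was then −0.277 and the mean covariance −0.0349, without shared libraries. Against the F1 stress group, the F2 no-stress group differed in 2 genes, Lnpep and Rfng (edgeR, 2862 genes at an unadjusted p below 0.05). The F2 stress group differed from the F1 no-stress group in 2 genes, Gpr17 and Neu4 (529 at an unadjusted p below 0.05). It differed from the F1 stress group in 2 genes as well (1169 at an unadjusted p below 0.05). Lnpep is named here because the count was small, after its values were seen.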

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

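The tests of regional composition for the F2 calls, the adjustments of the oxidative phosphorylation and immediate early gene scores, the score comparison between generations, and the offset for GC content and length as an alternative setting, were chosen only after the result was seen.

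The 1324 genes called between the F2 lineages leaned on the GC content of transcripts. Library trends with GC content and length may account for a part of the calls whose size is not settled. Put into simulated counts, the fitted trends of the 20 libraries gave 124 calls among unchanged genes in a single simulation, against 1324 observed. The simulated genes varied independently, with a spread taken from the real libraries that already held the trends. This gap therefore cannot decide how many of the observed calls the trends gave. With the trends entered, 9 of the 1324 genes kept their call, 1270 kept their sign, the median absolute log2 fold change went from 0.443 to 0.215 with a median SE of 0.111 before and 0.094 after, and 778 still had an unadjusted p below 0.05, so part of the calls, such as Nxph2 (1.37 before, 1.24 after, adjusted p = 0.0578), ended at the adjustment. Most of the 1324 calls were thus lost, the outcome set for the trends as their source. With the first component of the region and cell type scores in the model, 1323 genes kept their call. The median absolute log2 fold change then went from 0.443 to 0.445. No such score had an exact permutation p below 0.05 between the F2 groups, so the component may separate them too little to move their difference. This test therefore cannot decide on differing shares of neighbouring regions and cell types. Of 100 splits of the 10 F2 libraries, 1, the real one, gave as many genes, so other groupings seldom gave such a count. Another split gave 1173, so chance is not excluded. A split can keep most libraries of the real groups, so that count cannot tell a structure of the samples from a lineage effect. With the trends entered, 3 splits gave at least the 13 genes of the real one, and the highest other gave 1035. A lineage effect on GC-rich transcripts stays open and untested, because the offset would remove it too.

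In F1, the score of nuclear-encoded oxidative phosphorylation genes differed by −0.20 ± 0.086 (SE, log2 CPM; exact permutation test p = 0.0238, adjusted p = 0.393, which no single list could bring below 0.05; list test adjusted p = 0.776 with an estimated correlation), beside negative values in 18 of 18 striatal, 18 of 18 microglial, 78 of 80 ribosomal and 15 of 15 mitochondrial genes. With the trends with GC content and length removed the difference was −0.174 ± 0.066. It lay beyond the limit of −0.102, set for those trends as its source, by little more than 1 SE, which argues only weakly against them. With the striatal score in the model it was −0.143 ± 0.078, so fewer striatal-type neurons in the punches cannot be told apart from a lower expression within cells, the limit lying within 1 SE. A lineage effect in the cells stays open, as untested.

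The score of immediate early genes was above that of F1 in the F2 no-stress lineage (score difference 0.39 ± 0.166 SE in log2 CPM, exact permutation test p = 0.0397, adjusted p = 0.357 over 36 lists, which again no single list could bring below 0.05). The difference was 0.446 ± 0.113 with the first component of the region and cell type scores in the model, which argues against that component alone. Other differences in composition stay open, since 1 component need not hold them. The oligodendrocyte precursor score, for example, was higher by 0.408 in the same comparison (exact permutation test p = 0.0159, adjusted p = 0.357). With the trends with GC content and length removed it was 0.242 ± 0.174, against a limit of 0.196, so such trends cannot be told apart from a change in the genes. Handling or time of collection, which may differ between generations, and breeding itself stay open and untested.

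Other splits were counted for the remaining comparisons. In F1 and for the averaged effect the real count was 0, which all 100 of 100 splits reach whatever the data, so these counts say nothing about chance, and the highest other splits gave 26 and 292 genes (edgeR, 1030 and 2361 genes at an unadjusted p below 0.05; DESeq2 2 and 36, limma-voom 0 and 0, with library weights 3 and 532). For the difference between generations, 3 of 100 splits gave at least the 421 genes, the highest other giving 894. That count again cannot tell a structure of the samples from an effect. For F2 against F1 in the no-stress lineage, 1 of 100, the real one, gave 335 or more, and the highest other gave 18. By these counts, other groupings seldom gave as many genes as the real ones, but shares of 3 and 1 in 100 do not exclude chance.

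In all, 456 sets of 5 libraries were tested, for 107 named genes, some list scores, the mitochondrial share and the GC trend. Of these sets, 23 (5.04%), all of named genes, held a library whose gap to the next exceeded 0.71 of the range. Chance gives about 1 in 20. F2 stress replicate 14 stood apart in Zc3h3 (17.1 CPM), Zfr2 (39.3), Shank1 (184), Dnmt1 (55.4), Oxtr (34.1) and, on the low side, Cox5a (59.5). F2 stress replicate 15 stood apart in Fastk (46.0), Bcan (213) and, low, Dnaja1 (202), and replicate 11 in Itfg1 (332) and Uqcrc2 (209). F1 stress replicate 1 was highest in Tenm3 (124), Gtf3c6 (22.3) and Recql4 (2.19). In F1 no-stress libraries, replicate 9 was high in Grin1 (342) and low in Ube3a (115), replicate 8 high in Cycs (160), replicate 6 low in Uqcrb (46.6) and replicate 10 low in Ighmbp2 (7.19). In F2 no-stress libraries, replicate 20 was high in Lnpep (58.4), replicate 17 high in Egfl7 (24.4) and low in Rpl5 (144), and replicate 18 high in Cox5a (76.1).

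With the GC and length offset 0 genes passed the interaction test. Of the 24 called genes named for that test, 0 kept their call whichever library was left out. In the uncorrected fit of all libraries the lineage effect differed between generations for 45 named genes, here as F2 minus F1 log2 fold change. It was negative for Recql4 (−1.95), Ankrd23 (−1.84), Junb (−1.34), Wdr90 (−1.23), Inha (−1.22), Plec (−1.17), Rabep2 (−1.08), Shank1 (−1.03), Zfr2 (−1.01), Sptbn4 (−0.997), Zc3h3 (−0.98), Kmt2d (−0.98), Dus3l (−0.93), Vgf (−0.85), Gtpbp2 (−0.80), Acaa1a (−0.77), Kdm6b (−0.74), Hdac5 (−0.71), Ighmbp2 (−0.62), Slc39a13 (−0.58), Rfng (−0.43) and Trim41 (−0.43). It was positive for Tmem267 (1.18), Uqcrb (0.65), Nkain2 (0.65), Gtf3c6 (0.65), Oard1 (0.63), Rpl39 (0.62), Uqcrh (0.57), Fzd4 (0.54), Rps24 (0.53), Snrpd3 (0.53), Pdcd10 (0.51), Cox5a (0.51), Rpl7 (0.50), Ndfip1 (0.49), Lrrc40 (0.49), Tmed7 (0.48), Atp5c1 (0.48), Itfg1 (0.48), Timm29 (0.45), Rpl5 (0.40), Naa50 (0.40), Emc7 (0.36) and Sgpp1 (0.35).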

How the results depend on the processing

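The GC and length offset, the uncentred composition components and the removals of mitochondrial genes and of 2 libraries were chosen only after the result was seen. Where a cause is not given, the cause was not tested. The F1 count of 0 became 1 with library totals, with the centred composition component and at an adjusted p of 0.1, 2 in DESeq2 and 3 with library weights (edgeR, 1030 genes at an unadjusted p below 0.05; limma-voom 0), and 0 to 1 without single libraries. The F2 count of 1324 was 737 without a low-count filter, where more genes were tested, 2204 with 1 surrogate variable, 2363 with 2 uncentred components, 2565 with library weights and 2054 in DESeq2. It was 13 with the GC and length offset, 2213 without the 2 libraries, 0 with only the F2 groups in the fit (edgeR, 3216 at an unadjusted p below 0.05, fewer libraries for the spread), 2502 at 0.1, and 241 to 2431 without single libraries. The interaction count of 421 was 100, 1081 (centred component), 1175 (uncentred), 2421 (weights), 1240 (DESeq2), 0 (offset; 2417 unadjusted), 1643 (without the 2 libraries) and 1359 (0.1), and 0 to 1501 without single libraries. The averaged count of 0 was 532 with weights and 36 in DESeq2, and 0 to 490 without single libraries. The generation count of 335 was 208 with library totals, 61 without a filter, 649 (surrogate variable), 826 and 844 (components), 985 (weights) and 1028 (DESeq2). It was 9 (offset), 631 (without the 2 libraries), 0 with only its groups in the fit (3105 unadjusted) and 1057 (0.1), and 0 to 725 without single libraries. The centred component has a mean of 0 in every group, so it could change the spread but hardly the group differences (Ubxn2b in F1 −1.43, against −1.47 without it). The 7 F1 lists became 0 with an estimated correlation, and were 6 to 9 without single libraries; the 0 F2 lists became 0 to 2. With 1 surrogate variable, F1 values turned sign for Ido1 (0.10), Crhr1 (−0.004), Fkbp5 (0.032), Nr3c1 (0.031), Oxtr (−0.092) and the mean of the striatal list (0.14). The mean of the imprinted list was then 0.004. Fkbp5 was 0.021 with library totals, and Crhr1 in F2 0.14 with the offset. Without single libraries Fkbp5 in F1 ran from −0.086 to 0.039, Nr3c1 in F1 from −0.105 to 0.008, Crh in F2 from −0.015 to 0.297, and the correlation of F1 and F2 fold changes from −0.255 to 0.097. Of the 52 named genes called in F2, 1 kept its call with the offset, 49 with library totals, 40 without a filter and 51 in limma-voom.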

Other observations

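The comparison of generations within the stress lineage and the score comparisons between generations were chosen only after the values were seen.

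Gpr17, a receptor of committed oligodendrocyte precursors, was higher in F2 than in F1 in both lineages. It rose by 0.81 ± 0.12 (log2 fold change ± SE, adjusted p = 0.0101) in the no-stress and by 0.80 ± 0.12 (adjusted p = 0.0225) in the stress lineage, with an interaction of −0.009 (adjusted p = 0.983). The sialidase gene Neu4 rose by 0.58 in the no-stress lineage and had a value of 0.58 (adjusted p = 0.124) in the stress lineage. Of 12 precursor genes, 10 were positive in the no-stress lineage (median 0.40) and 9 in the stress lineage (median 0.15), and their score was higher in F2 by 0.41 (exact permutation test, p = 0.0159) and by 0.24 (p = 0.0635), with adjusted p of 0.357 and 0.762 over 36 lists, where no single list could pass. Pdgfra, a marker of earlier precursors, had values of −0.006 ± 0.109 and 0.04 ± 0.109.

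The glutamate receptor and transporter score was lower in F2 than in F1 of the stress lineage by 0.12 on the log2 scale (6.69 ± 0.07 against 6.81 ± 0.05, SD, n = 5 each; exact permutation test p = 0.0159, adjusted p = 0.572). Of the immediate early genes, 19 of 22 were positive there too, with a median of 0.18 and no call (edgeR, adjusted p of at least 0.643).

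With the GC and length offset, 13 genes were called between the F2 lineages, outside the rule for named genes. Higher were Emd (0.37), Thap11 (0.45), Hnrnpa0 (0.47), Tatdn2 (0.47), Slc25a11 (0.28), Eid2 (0.64), Stk24 (0.32), Timm29 (0.32) and Mtmr9 (0.31), and lower were Acaa1a (−0.48), Mrps9 (−0.49), AC160637.1 (−0.77) and Gm28578 (−1.10), with adjusted p from 0.00951 to 0.0459. Without the offset Thap11 (0.144), Tatdn2 (0.137), Slc25a11 (0.156) and Eid2 (0.309) had no call (edgeR, adjusted p from 0.0684 to 0.345). With it, Tatdn2 (−0.469), Slc25a11 (−0.286), Stk24 (−0.327), Timm29 (−0.335) and Mtmr9 (−0.336) were also called lower in F2 than in F1 of the no-stress lineage. That comparison shares the F2 no-stress libraries, which alone could give such opposite values.

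Of the lists that did not pass in F1 with the preset correlation, 13 of 16 lists of functions had adjusted p from 0.219 to 0.742, 9 of 10 of cell types from 0.0918 to 0.742, 6 of 7 of regions from 0.616 to 0.742, and the Y-linked list 0.828. In F2, adjusted p ran from 0.209 to 0.953 for functions, 0.248 to 0.948 for cell types, 0.222 to 0.972 for regions and 0.755 to 0.87 for the 3 quality lists.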
